A study of Homo sapiens with 4 samples.

How the data were processed

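Germinal center B cells had been sorted by flow cytometry from normal lymph nodes, and biotin-labelled RNA was hybridised to 4 Affymetrix arrays, 1 per sample, per the labels. Per the series design the samples came from 3 individuals, 1 of them sampled more than once. The sorting markers and the pairing of arrays with individuals are not given in the sources used here. All 4 arrays formed 1 group, named here by the replicate numbers of their titles.

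The deposited values are log2 signals per probe set that the authors made by robust multi-array averaging (RMA), per the submitters' processing notes. RMA subtracts a modelled background, forces the arrays to a shared distribution and summarises the probes of a set on the log2 scale. It therefore removes any difference in total signal between arrays and compresses differences between dim genes. The software, its version and the set of arrays processed together are not given in the sources used here. The deposited medians differed slightly between arrays, and no detection calls were used here. The scale was checked against the range of the values.

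Probe sets were named from the platform annotation. Of 22283 probe sets, 19071 had 1 gene symbol and 1043 had several. Another 2169, including 68 control probe sets, were not listed in that table and stay unnamed here. Symbols were matched by gene identifier to a reference gene table of assembly GRCh38.p14 for 19059 probe sets, and the match changed 0 symbols. No coordinates were used. A gene took the value of its probe set with the highest mean over the 4 arrays, and 4310 genes had more than 1 probe set. No gene was named from a probe set with several symbols. XIST, Y-linked genes and genes of common inherited presence or absence or strong allelic variation (HLA class I and variable class II chains, KIR, immunoglobulin and T cell receptor segments and the like) were left out of every listing.

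Without detection calls, the background level of an array was set as the 95th percentile of its 51 probe sets for olfactory and taste receptor genes, which lymphocytes were taken not to use. The difference between a gene's log2 signal and this level was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a two-sided moderated test over the 4 arrays, with Benjamini-Hochberg adjustment over 11963 genes). An adjusted p under 0.05 with a positive mean was called above background, with a negative mean below it. A gene counted as at background when each of its probe sets lay at or below the level on all 4 arrays, and as high when it lay in the top 5% of genes on each array. Being at background shows only that no probe set rose above the reference, not that the transcript was missing. The level is itself an upper percentile of probe sets taken as silent, so most silent genes fall significantly below it. The test was also run on simulated data with the spread of the 11963 genes and 50 genes moved at each of 4 shifts. As above background it recovered 26%, 64%, 98% and 100% of genes shifted by 0.5, 1, 2 and 3 log2. Of all its calls, above or below the level, 4.64% were false. The simulated noise was independent between arrays, the level was known without error and 11763 genes lay exactly at it. None of this holds for the data, so the share of false calls there may differ.

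Before the data were examined 40 gene lists were fixed, 27 by name (cell types, zones of the germinal center, cell cycle, repair, signalling, apoptosis and others) and 13 by symbol pattern. Of 550 entries in the named lists 473 were measured under a single name. For 39 lists the share of members among high genes and among genes at background was tested against all other genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 78 tests). The receptor list sets the background level and was not tested. Genes are not independent replicates, so these tests describe the lists on these arrays. Adjusted over the list alone, the number of members above background was the same as over all genes for each of the 40 lists. For each array a list's median deviation from its genes' means was set against 10000 random lists matched on mean signal in 20 bins. Pearson's r between arrays was taken over all probe sets. Lists and draws were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were made with matplotlib 3.10.9.

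Genes named in the text follow a rule also fixed beforehand. It takes up to 6 members of each list (up to 20 for the germinal center list), with at least the highest and the lowest mean. It adds the 15 highest means outside ribosomal, respiratory, translation factor, mitochondrial, HLA and immunoglobulin genes, and the 10 largest SDs among genes above background. Members between the highest and the lowest were chosen after their values were seen. Several whose calls changed between settings were then left out of the text for brevity, so stability is also counted over all list genes.

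Alternatives set beforehand left out each array, averaged each of the 6 possible pairs of arrays as 1 sample, took the median probe set per gene and dropped probe sets whose type can bind several transcripts (suffix x or s). They also repeated quantile normalization, subtracted array medians, and set the background at the 90th or 99th percentile or from genes of unrelated tissues. Trended and robust limma fits and top 10% and top 2% classes were run as well. A set of T cell genes outside the lists, 13 of them measured, was chosen to test for T cells before their own values were looked at but after the T cell list was. Leaving out arrays 3 and 4 together was added after their control probe sets were seen.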

Results

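Messenger RNA was profiled in germinal center (GC) B cells, the dividing B cells that mutate and select their antibody genes inside lymphoid follicles. The cells were sorted by flow cytometry from normal human lymph nodes. The data comprise 4 Affymetrix arrays from 3 individuals, of whom 1 was sampled more than once, and all 4 arrays form a single group. The labels do not say which arrays share an individual, so p-values measure the spread between these 4 arrays, part of which may be technical. The stated aim was to list genes that are strongly expressed or silent in these cells. Each gene was therefore set against the array's own background level, and no contrast with another cell type could be made. Signals are log2 values from robust multi-array averaging (RMA), given as mean ± SD over the 4 arrays (n = 4) unless an array is named. The number of arrays limits the precision of every value.

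The arrays held 22283 probe sets, of which 19071 named 1 gene, and these covered 11963 genes. Median signals were 4.28, 4.27, 4.34 and 4.42 on arrays 1 to 4, and signals ranged from 2.57 to 14.2 over all arrays. The background level, the 95th percentile of 51 probe sets for olfactory and taste receptors, was 4.67, 4.77, 4.84 and 4.87. Pearson's r over all probe sets was 0.996 between arrays 1 and 2 and 0.981 between arrays 3 and 4. The other pairs gave 0.972 for arrays 1 and 3, 0.957 for arrays 1 and 4, 0.973 for arrays 2 and 3, and 0.957 for arrays 2 and 4. Genes above background had a median SD of 0.27, genes at background 0.15, and 811 of the genes above background (15.9%) had an SD over 0.5.

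The arrays differed in the 3' to 5' balance of control probe sets. For the cytoskeletal control ACTB, the probe set at the 3' end exceeded that at the 5' end by 1.40, 1.38, 3.56 and 6.73 log2 on arrays 1 to 4. For the glycolytic control GAPDH the same difference was 0.61, 0.66, 1.99 and 4.55. The polyadenylated spike-in phe gave 1.93, 1.80, 2.02 and 3.18, so it moved little on array 3, and lys gave 0.60, 0.66, 0.93 and 1.33. Arrays 3 and 4 thus held less signal at the 5' ends of ACTB and GAPDH, for a reason that was not tested, and this stands beside every value that differs between arrays.

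**Figure D1:**
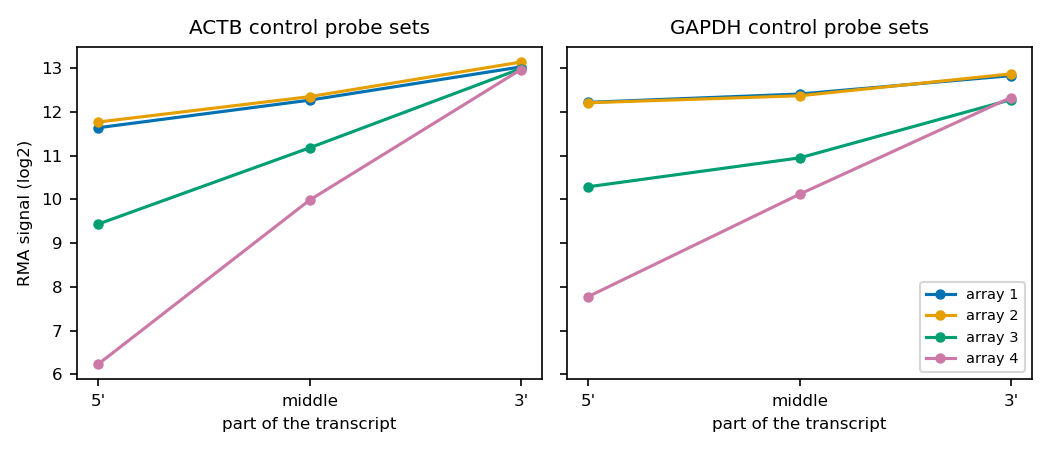
Signals (log2, vertical axis) of the 5', middle and 3' control probe sets of ACTB and GAPDH (horizontal axis), with a line per array. The 3' signals lie close together, while the 5' signal of ACTB is 11.6 on array 1, 11.8 on array 2, 9.44 on array 3 and 6.24 on array 4.

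Of the 11963 genes, 5105 (42.7%) lay above background and 5390 (45.1%) lay at or below it with every probe set on every array. By limma with Benjamini-Hochberg adjustment 5374 genes lay below the background level and 1484 on neither side. The level was set on single probe sets, whereas a gene took its brightest, which favours calls above it for genes with several. With the median of a gene's probe sets 4354 genes lay above background and 6148 at it on every array. On all 4 arrays 477 genes (3.99%) were in the top 5% of signals, where identical orders would have given 598. Ribosomal proteins, the components of the ribosome, had 50 of 55 measured members there (Fisher's exact test, adjusted p = 1.9e-63), led by RPL41 at 14.08 ± 0.08, and RPL3L was lowest at 3.70 ± 0.11. Respiratory chain subunits, which drive mitochondrial ATP synthesis, had 38 of 64 (Fisher's exact test, adjusted p = 1.42e-35), including ATP5MG at 12.35 ± 0.21 and COX6A1 at 11.87 ± 0.09. ATP5MC2P1, a pseudogene that the symbol pattern of this list took in, lay at background. All 33 proteasome subunits lay above background and 12 were in the top class (Fisher's exact test, adjusted p = 3.47e-08), from PSMA7 at 10.46 ± 0.27 to PSMD10 at 6.54 ± 0.66. No proteasome subunit was in a top 2% class.

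Outside ribosomal, respiratory, translation factor, mitochondrial, HLA and immunoglobulin genes, the 15 highest means lay between 12.49 and 13.64. TPT1, a translationally controlled protein, had 13.64 ± 0.10, ACTB 13.47 ± 0.08 and GAPDH 13.00 ± 0.57. Ubiquitin precursor UBB had 12.97 ± 0.12, the poly(A)-binding protein PABPC1 12.89 ± 0.02, and FAU, a ribosomal fusion protein, 12.75 ± 0.24. The actin regulators TMSB4X, TMSB10 and CFL1 had 12.85 ± 0.07, 12.71 ± 0.29 and 12.68 ± 0.24. PPIA, a prolyl isomerase, had 12.70 ± 0.35 and the tubulin gene TUBA1B 12.52 ± 0.54. LAPTM5, a lysosomal protein of lymphocytes, had 12.54 ± 0.22, the MHC class I light chain B2M 12.49 ± 0.17 and NACA 12.49 ± 0.28. The ubiquitin ligase HUWE1 had 13.05 ± 0.06 by 1 probe set, whereas its other 3 probe sets had means of 7.60, 3.70 and 3.43, so that its place rests on a probe set of a kind that can bind related transcripts. All of these 15 genes except UBB and CFL1 rest on probe sets of that kind (suffix x or s). NACA had 4.11 ± 0.49 by its only probe set without such a suffix. Rank among genes reflects probe affinity as well as transcript amount.

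The identity of the sorted cells was addressed with a list of GC B cell genes and a list of genes shared by B cells. Of 22 measured GC genes 20 lay above background and 4 were in the top class (Fisher's exact test, adjusted p = 0.0237). POU2AF1, a coactivator of octamer transcription factors needed for GC formation, had 11.70 ± 0.03. LMO2 had 10.14 ± 0.27, ELL3 10.01 ± 0.51 and the adaptor STAP1 9.43 ± 0.30. BCL6, the repressor that defines the GC program, had 9.29 ± 0.64, and RGS13, a regulator of chemokine receptor signalling, 9.43 ± 0.60. CD38 had 8.53 ± 0.67, MYBL1 8.16 ± 1.18, BACH2 7.70 ± 0.82 and the histone methyltransferase EZH2 7.01 ± 1.21. The migration receptor S1PR2 (4.27 ± 0.34) and the G protein subunit GNA13 (4.08 ± 0.22) lay below the background level although both are known to act in these cells, which an insensitive probe set would also give.

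MME, the surface peptidase CD10 of GC B cells, had 6.96, 7.20, 5.46 and 5.17 on arrays 1 to 4 and lay above background by limma (adjusted p = 0.0187). That call was lost without array 1 (limma, adjusted p = 0.0686) or without array 2 (0.0597). Among 19 measured B cell genes 18 lay above background and 7 were in the top class (Fisher's exact test, adjusted p = 3.05e-05). They included VPREB3 at 11.10 ± 0.35, the antigen receptor subunit CD79B at 10.62 ± 0.40, the B lineage factor PAX5 at 10.10 ± 0.13, the surface protein MS4A1 (CD20) at 9.98 ± 0.74 and the inhibitory receptor CD22 at 9.53 ± 0.19. RALGPS2 was the 1 member at background (3.42 ± 0.26). With a top 2% class the enrichments of the GC and B cell lists were lost (Fisher's exact test, adjusted p = 0.501 and 0.0718).

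**Figure D2:**
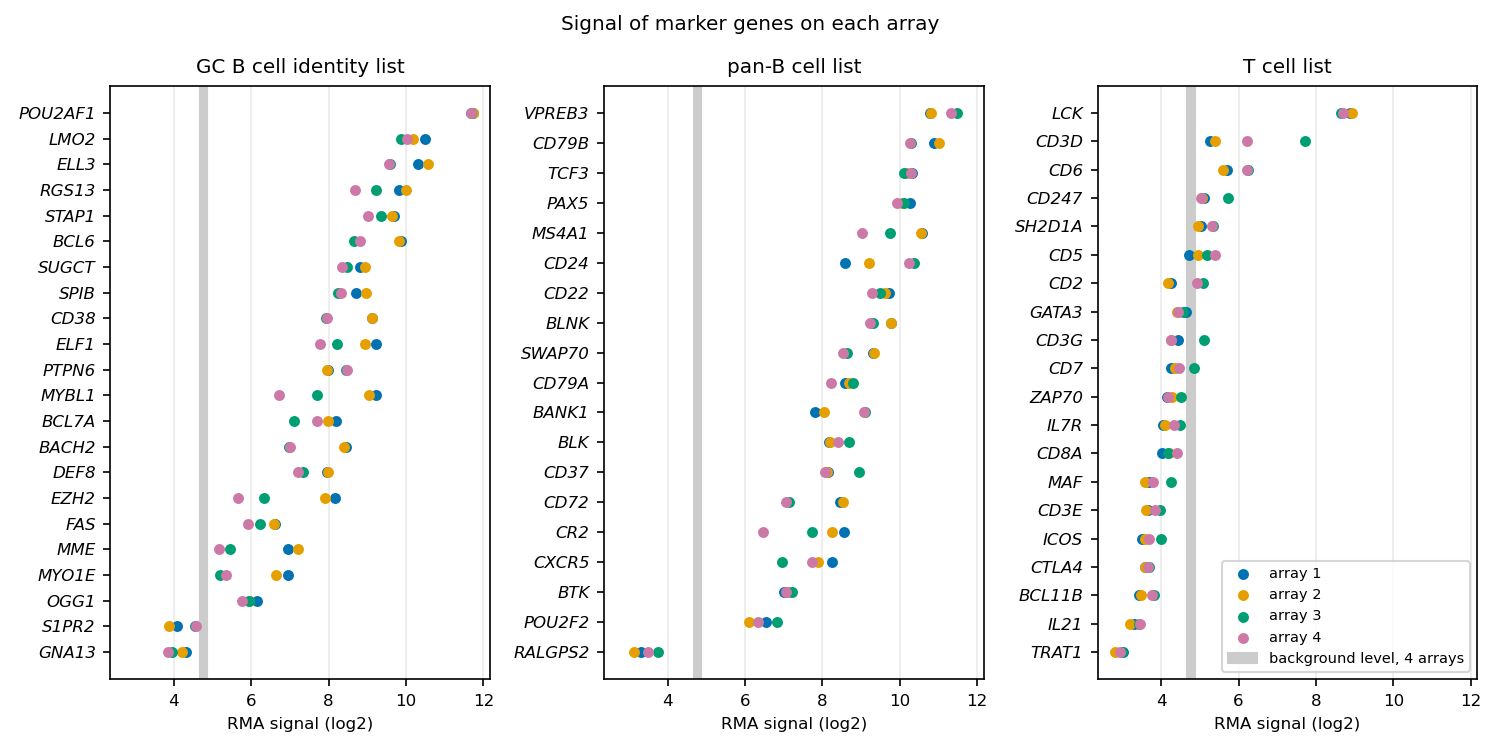
Signal (log2, horizontal axis) of each measured member of the GC B cell, pan-B cell and T cell lists, with a point per array and the range of the background levels of the 4 arrays in grey. The lists have 20 of 22, 18 of 19 and 6 of 20 members above background.

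Proliferation genes, which report cells copying DNA or dividing, were nearly all above background. Of 26 measured S phase genes 23 lay above it and none at background on every array (Fisher's exact test, adjusted p = 1.74e-06), while 4 were in the top class (adjusted p = 0.0363). The sliding clamp PCNA had 10.47 ± 0.53, TYMS, which makes thymidylate, 10.31 ± 0.33, RRM2, a ribonucleotide reductase subunit, 10.04 ± 0.41 and the replicative helicase subunit MCM5 9.51 ± 0.28. MCM4 had 8.07 on array 1 and 5.56 on array 4 and was not called with the median of its probe sets (limma, adjusted p = 0.307), and cyclin CCNE2 was lowest at 4.64 ± 0.70. Of 30 genes of G2 and mitosis 27 lay above background and none at background on every array (Fisher's exact test, adjusted p = 1.87e-07), while 2 were in the top class (adjusted p = 0.506). That class was enriched without probe sets of suffix x or s (Fisher's exact test, adjusted p = 0.0286), with a top 10% class (0.0165) and without arrays 3 and 4 (0.00592). PTTG1 (securin) had 11.25 ± 0.28, the mitotic kinase CDK1 8.75 ± 0.29, topoisomerase TOP2A 8.39 ± 1.05 and the proliferation antigen MKI67 6.35 ± 0.79, while TTK had 5.50 ± 0.98 and PLK1 4.42 ± 0.41. PLK1 lay below the background level without array 1 (limma, adjusted p = 0.03). With the median of a gene's probe sets the S phase list was no longer enriched in the top class (Fisher's exact test, adjusted p = 0.408).

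Cell cycle inhibitors had 6 of 9 members above background, among them CDKN1B at 6.98 ± 0.25 and CDKN1A at 6.74 ± 0.60, with CDKN2B lowest at 3.39 ± 0.17, and neither class test passed. DNA repair genes, which act on the lesions of antibody gene mutation and switching, had 13 of 20 above background and 2 at background (Fisher's exact test, adjusted p = 0.00355), a depletion lost without probe sets of suffix x or s (adjusted p = 0.0958). The end-joining factor XRCC6 had 9.87 ± 0.43, the abasic site nuclease APEX1 9.78 ± 0.08, the mismatch protein MSH6 8.84 ± 0.62 and the ligase LIG4 3.38 ± 0.14. MSH6 was not called with the median of its probe sets (limma, adjusted p = 0.822). UNG, which removes uracil from DNA, had 6.05, 6.04, 5.25 and 4.39 on arrays 1 to 4 and was not called, although it lay above background without array 4 (limma, adjusted p = 0.00752).

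Division genes are most active in the dark zone of the GC and activation genes in the light zone. Dark zone genes lay above background for 9 of 11 members and at background for 1 (Fisher's exact test, adjusted p = 0.0328), a call lost without array 1 (adjusted p = 0.134). In the top class were 2 members (Fisher's exact test, adjusted p = 0.122). That class was enriched without array 3 (adjusted p = 0.0212), with the median probe set (0.0175) and without arrays 3 and 4 (0.00324), but not without array 1, 2 or 4 alone. The retention receptor CXCR4 had 10.98 ± 0.11, cyclin CCNB1 8.19 ± 0.89 and the transcription factor FOXO1 7.83 ± 0.06, and the polymerase POLH was lowest at 3.96 ± 0.13. The small SDs of CXCR4 and FOXO1 hold for their brightest probe sets only. Between arrays 1 and 4 the other probe sets of CXCR4 fell from 10.62 to 8.31 and from 10.18 to 8.53. That of FOXO1 fell from 7.56 to 6.91. Light zone genes lay above background for 12 of 17 members and at background for 2 (Fisher's exact test, adjusted p = 0.0144). The activation marker CD83 had 10.04 ± 0.24, the survival gene BCL2A1 8.45 ± 0.40, MYC 8.32 ± 0.39 and CD40 7.66 ± 0.76, while CCND2 (5.34 ± 1.26) was not called and EGR3 (4.03 ± 0.31) lay at background. In all 8 dark zone members and 6 light zone members also stand in other lists, so these counts are not independent of those for mitosis and NF-kB.

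Antigen receptor signalling genes were abundant. Of 17 members 16 lay above background, 6 were in the top class (Fisher's exact test, adjusted p = 0.000161) and none lay at background on every array (adjusted p = 0.000284). The kinases LYN, SYK and BTK had 9.85 ± 0.02, 8.59 ± 0.30 and 7.11 ± 0.10, the phospholipase PLCG2 had 9.59 ± 0.31, and VAV2 was not called at 4.95 ± 0.22, or called below the level with the median of its probe sets (limma, adjusted p = 0.00137). Without probe sets of suffix x or s the enrichment in the top class was lost, with 2 of 8 members left there (Fisher's exact test, adjusted p = 0.073). Genes of MHC class II presentation lay above background for 10 of 11 members, with 4 in the top class (Fisher's exact test, adjusted p = 0.00223). The invariant chain CD74 had 12.02 ± 0.29, HLA-DRA 11.69 ± 0.76, the peptide exchanger subunit HLA-DMA 10.88 ± 0.05 and the transactivator CIITA 5.68 ± 0.48, while RFXAP lay at background (3.73 ± 0.11). The CIITA call came from 1 of 3 probe sets and reversed with their median.

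NF-kB components and targets lay above background for 13 of 16 members and none lay at background on every array (Fisher's exact test, adjusted p = 0.000521). The feedback inhibitor TNFAIP3 had 8.08 ± 0.15, the subunit RELA 7.28 ± 0.35 and NFKB2 4.94 ± 0.30, the last not called except without array 4 among the fits that left out 1 array (limma, adjusted p = 0.0157). With the median of its probe sets NFKB2 was called below the level (limma, adjusted p = 0.00585). Immediate early and dissociation stress genes, which respond within minutes to signals and to handling of tissue, had 13 of 15 members above background and 5 in the top class (Fisher's exact test, adjusted p = 0.000829). They included the phosphatase DUSP1 at 11.71 ± 0.40 and the transcription factors JUN, FOS and EGR1 at 10.64 ± 0.46, 9.85 ± 0.24 and 8.87 ± 0.30, while IER3 lay at background (4.13 ± 0.20). With the median of a gene's probe sets 2 members were in that class and the enrichment was lost (Fisher's exact test, adjusted p = 0.192).

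Pro-apoptotic genes lay above background for 14 of 15 members and at background for 1 (Fisher's exact test, adjusted p = 0.00774). Cytochrome c (CYCS) had 9.40 ± 0.09, PMAIP1 (NOXA) 9.16 ± 0.70, BAX 6.80 ± 0.45 and the initiator caspase CASP8 3.97 ± 0.40. The depletion was lost with the median of a gene's probe sets, when 4 members lay at background (Fisher's exact test, adjusted p = 0.129). Anti-apoptotic genes lay above background for 6 of 9 members and at background for 3, with no class enriched or depleted. MCL1 had 9.68 ± 0.08, BCL2A1 8.45 ± 0.40 and XIAP 3.55 ± 0.09. BCL2, which GC B cells are known to switch off, had 5.60 ± 0.29 and an adjusted p of 0.000858 by limma. Without array 1 or array 2 another of its probe sets had the highest mean and the call was lost (limma, adjusted p = 0.188 and 0.211); that probe set had 3.76, 3.97, 6.78 and 6.62 on arrays 1 to 4. The MCL1 call reversed with the median of its 5 probe sets.

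Genes of other B cell stages gave a mixed picture. Naive and memory B cell genes lay above background for 13 of 18 members and at background for 2 (Fisher's exact test, adjusted p = 0.00931). TCL1A had 11.54 ± 0.71, TXNIP 10.49 ± 1.27, IL4R 9.18 ± 0.59 and the quiescence factor KLF2 8.85 ± 1.25, while the homing receptor CCR7 (5.09 ± 1.35) was not called and S1PR1 lay at background (3.52 ± 0.31). Without arrays 3 and 4, a setting chosen after the values were seen, 5 members lay at background and the depletion was lost (Fisher's exact test, adjusted p = 0.157). Plasma cell genes lay above background for 7 of 14 members and at background for 5, with no class enriched or depleted. The joining chain JCHAIN had 9.27 ± 0.28 and the secretory regulator XBP1 6.93 ± 0.16, IRF4 (5.06 ± 0.37) was not called, and SDC1 (4.30 ± 0.36) and CAV1 (3.33 ± 0.17) lay at background. PRDM1, which drives plasma cell differentiation, had 5.05 ± 0.23 (limma, adjusted p = 0.034), and its call was lost on leaving out any 1 array (adjusted p from 0.0528 to 0.0873). Without array 4 IRF4 was called above background (limma, adjusted p = 0.0262), with the median of its probe sets it was called below the level (0.0144), and without array 1 SDC1 was no longer called below it (0.0522).

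Markers of cells outside the B lineage were mostly at background. NK and cytotoxic genes had 0 of 13 members above background by limma, also at an unadjusted p under 0.05, and 11 at background (Fisher's exact test, adjusted p = 0.0115). CTSW had 4.62 ± 0.22, GNLY 3.74 ± 0.34, NKG7 3.64 ± 0.26, GZMB 3.46 ± 0.26 and KLRF1 3.35 ± 0.20, and CTSW was called below the level without array 4 (limma, adjusted p = 0.047). Myeloid genes had 12 of 15 at background (Fisher's exact test, adjusted p = 0.019), including CD14 (3.85 ± 0.15), C1QA (3.70 ± 0.21) and LYZ (3.18 ± 0.26), and 1 above it, AIF1 at 7.32 ± 0.43. Endothelial genes had 8 of 9 at background (Fisher's exact test, adjusted p = 0.0297) and 0 above it by limma, also at an unadjusted p under 0.05, from ROBO4 at 4.75 ± 0.50 to VWF at 4.16 ± 0.32 and CDH5 at 3.07 ± 0.12. With the background at the 90th percentile the NK and endothelial enrichments were lost (Fisher's exact test, adjusted p = 0.775 and 0.0684).

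T cell genes lay above background for 6 of 20 members and at background for 11 (Fisher's exact test, adjusted p = 0.558). LCK, a kinase of T cells that some B cells also hold, had 8.79 ± 0.14. The CD3 subunit CD3D had 5.26, 5.40, 7.72 and 6.21 on arrays 1 to 4, and its call was lost without array 4 (limma, adjusted p = 0.0506). CD247 had 5.12, 5.06, 5.73 and 5.02 and its call was lost without array 1 (limma, adjusted p = 0.0664). CD3G had 4.43, 4.25, 5.11 and 4.25 and was called below the level without array 3 (limma, adjusted p = 0.017), and TRAT1 was lowest at 2.93 ± 0.09.

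Stromal and follicular dendritic cell genes had 11 of 17 members at background (Fisher's exact test, adjusted p = 0.241), among them the follicle chemokine CXCL13 (3.24 ± 0.05), the collagen COL3A1 (3.28 ± 0.10) and LUM (2.96 ± 0.13). The 2 above it were COL1A1 (5.79 ± 0.23) and IGFBP7 (5.35 ± 0.34), both of which reversed with the median of their probe sets. With that median 16 stromal genes lay at background and the list was enriched there (Fisher's exact test, adjusted p = 0.00115), as it was with the 99th percentile (0.0274) or unrelated tissues (0.0285) as background. Epithelial genes had 8 of 10 at background (Fisher's exact test, adjusted p = 0.0918), including EPCAM (3.18 ± 0.04), and SFN above it at 7.48 ± 0.09 by 1 of 3 probe sets. Red cell and platelet genes had 6 of 8 at background (Fisher's exact test, adjusted p = 0.246), with GP9 above it at 5.43 ± 0.25 and PPBP lowest at 3.10 ± 0.07. The epithelial list passed the threshold without array 4, with 9 members at background (Fisher's exact test, adjusted p = 0.018), and with each other background level (0.0381, 0.0429 and 0.0443).

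Several developmental and tissue-restricted families were enriched among genes at background. HOX cluster genes, which pattern the body axis, had 22 of 24 members at background (Fisher's exact test, adjusted p = 1.74e-05), with HOXC4 above it at 5.64 ± 0.23 and HOXD12 lowest at 3.15 ± 0.13. HOXD9 (4.98 ± 0.08; limma, adjusted p = 0.0418) lost its call on leaving out any 1 array (adjusted p from 0.0631 to 0.138). Transcription factors of other lineages had 22 of 29 at background (Fisher's exact test, adjusted p = 0.00345), including the regulatory T cell factor FOXP3 (4.34 ± 0.30) and GATA6 (3.11 ± 0.08). The 3 above it were PAX8 (5.96 ± 0.09), GATA2 (5.75 ± 0.31) and TAL1 (5.02 ± 0.07), each of which reversed with the median of its probe sets. The enrichment of this list was lost with the background at the 90th percentile (Fisher's exact test, adjusted p = 0.299), and TAL1 lost its call without array 1, 2 or 3 (limma, adjusted p = 0.13, 0.072 and 0.0939).

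Cancer-testis antigens of the MAGE, GAGE and SSX families had all 17 members at background (Fisher's exact test, adjusted p = 9.09e-06) and 0 above it by limma, also at an unadjusted p under 0.05. MAGEC2 had 4.46 ± 0.26, called below the level except without array 1 or array 2 (limma, adjusted p = 0.0779 and 0.0677), and MAGEA6 was lowest at 3.11 ± 0.12. Keratins had 35 of 40 at background (Fisher's exact test, adjusted p = 4.68e-07), with KRT10 (8.06 ± 0.20) and KRTAP5-8 (5.87 ± 0.26) above it and KRTAP4-7 lowest at 2.94 ± 0.11. Genes of unrelated tissues had 41 of 52 at background (Fisher's exact test, adjusted p = 6.58e-06), down to the intestinal enzyme SI at 2.87 ± 0.12. The 5 above background were MBP (6.63, from 5.46 to 7.90 over the arrays), CYP3A4 (5.84 ± 0.27), GRIN1 (5.54 ± 0.56), AQP2 (5.26 ± 0.06) and SFTPC (5.26 ± 0.40). With the median of a gene's probe sets MBP, CYP3A4 and GRIN1 reversed, while SFTPC was no longer called (limma, adjusted p = 0.966). AQP2 has 1 probe set, so that setting could not change it. The calls of AQP2 and SFTPC were lost with the 99th percentile as background (limma, adjusted p = 0.349 and 0.295) and with unrelated tissues (0.223 and 0.28).

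Secreted immune mediators were also near background. Type I interferons had all 13 members at background (Fisher's exact test, adjusted p = 0.000161) and 0 above it by limma, also at an unadjusted p under 0.05, from IFNA17 at 4.17 ± 0.10 to IFNB1 at 3.59 ± 0.10 and IFNA8 at 2.78 ± 0.13. Interleukins had 22 of 29 at background (Fisher's exact test, adjusted p = 0.00345), including IL10 (3.44 ± 0.11) and IL33 (2.77 ± 0.09). Those above it were IL16 (3.21 above the level on average), IL23A (5.74 ± 0.31) and IL25 (5.12 ± 0.25), the last not called without array 2 or array 3 (limma, adjusted p = 0.0558 and 0.0589). With the median of its probe sets IL23A was not called (limma, adjusted p = 0.974). Chemokines had 26 of 32 at background (Fisher's exact test, adjusted p = 0.000201), including CXCL8 (3.32 ± 0.20) and CXCL6 (2.92 ± 0.13). CCL4 (6.29 ± 0.19) and CCL22 (5.45 ± 0.56) lay above it, and the CCL22 call was lost without array 3 or array 4 (limma, adjusted p = 0.0632 and 0.0599).

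**Figure D3:**
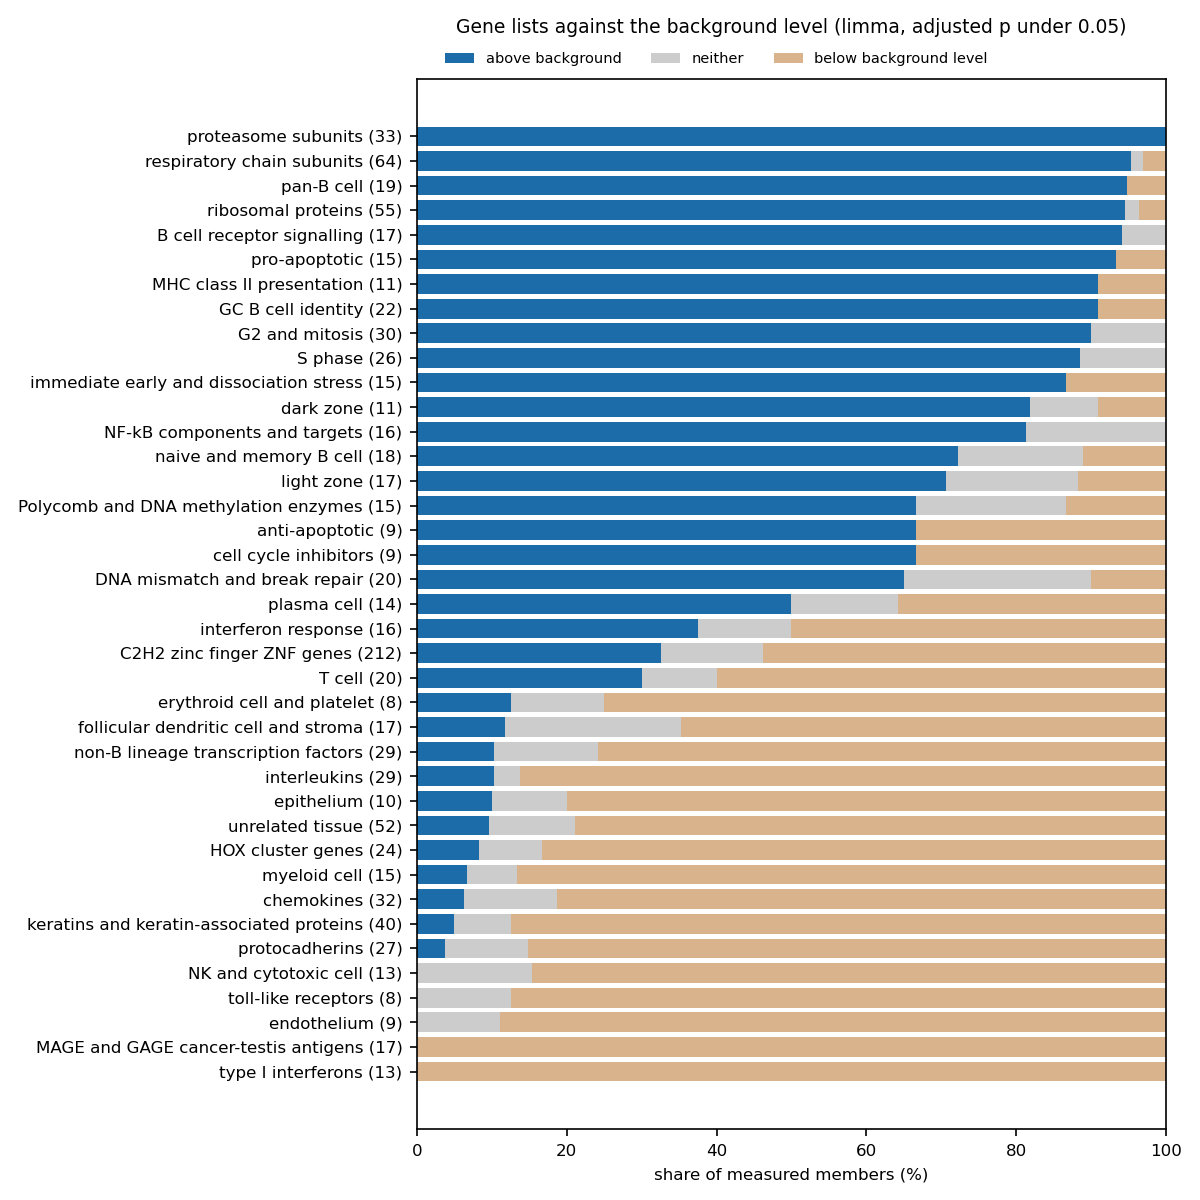
Share of measured members (%, horizontal axis) of each of the 39 tested gene lists that lay above background, below the background level or on neither side (limma, adjusted p under 0.05), with the number measured in parentheses. Proteasome subunits lie entirely above background, and type I interferons and MAGE and GAGE antigens entirely below the level.

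Values of whole gene groups differed between arrays. Each list's median deviation from its genes' means was compared with 10000 random lists matched on mean signal, and 33 of 160 list and array pairs lay outside the central 99% of the random values. On arrays 1 to 4 S phase genes deviated by 0.46, 0.49, -0.31 and -0.59 log2, and genes of G2 and mitosis by 0.49, 0.47, -0.58 and -0.42. GC identity genes deviated by 0.35, 0.38, -0.30 and -0.42, and naive and memory genes by -0.68, -0.53, 0.64 and 0.40. All medians of these lists lay outside the random range, and they stand beside the lower 5' signal of the controls on arrays 3 and 4. DNA repair genes deviated by 0.30 on array 1, 0.24 on array 2 and -0.43 on array 4, and dark zone genes by 0.38 on array 1 and -0.48 on array 3.

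Other lists departed on some arrays. T cell genes deviated by 0.22 on array 3, NK genes by 0.32 on array 4, plasma cell genes by -0.21 on array 1 and genes of unrelated tissues by 0.19 on array 4. Immediate early genes deviated by -0.18, -0.29 and 0.38 on arrays 1, 2 and 4, and ribosomal proteins by -0.18, -0.10 and 0.20 on arrays 1, 2 and 3. Proteasome subunits deviated by 0.29 on array 2 and respiratory chain subunits by -0.07 on array 1, which became -0.14 when quantile normalization was repeated. Genes that move together make random lists too narrow, so these percentiles describe the arrays and carry no p-value.

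**Figure D4:**
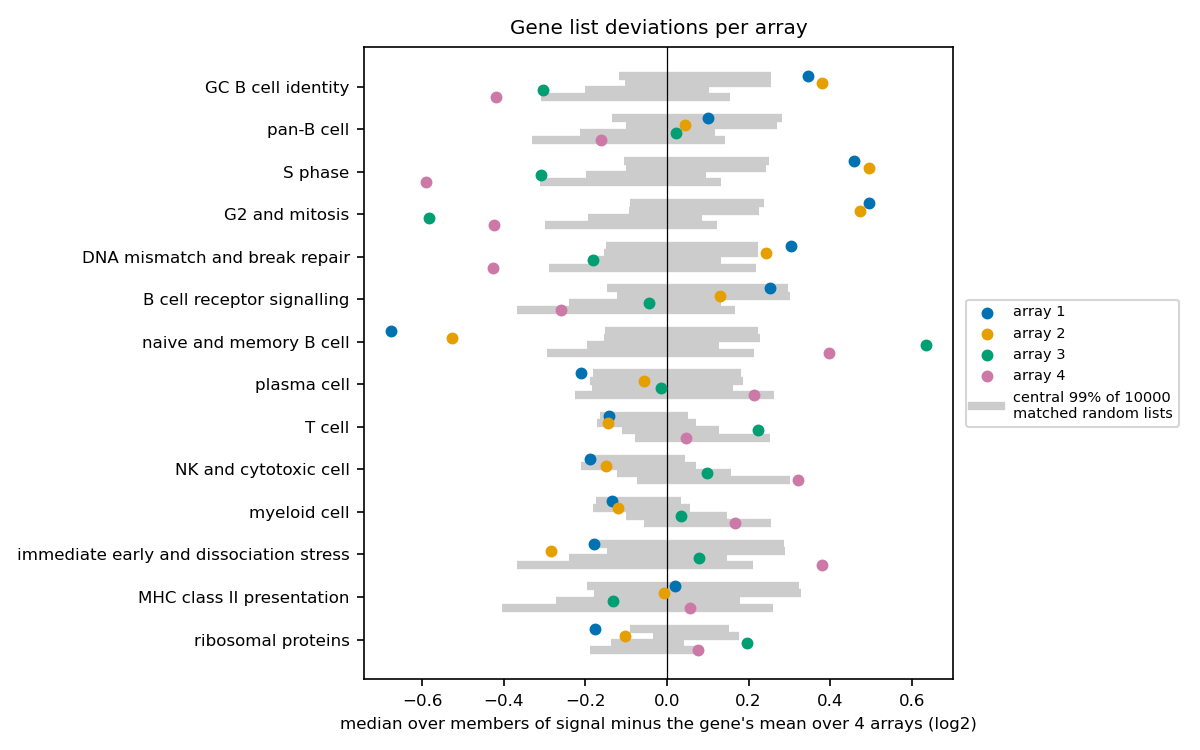
Median over list members of signal minus the gene's mean over the 4 arrays (log2, horizontal axis) for 14 gene lists, with a point per array and grey bars for the central 99% of 10000 matched random lists. S phase medians are 0.46 and 0.49 on arrays 1 and 2 and -0.31 and -0.59 on arrays 3 and 4.

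Among genes above background the 10 with the largest SD included 3 of the naive and memory list. FCMR, a receptor for IgM, had 7.93, 7.91, 10.34 and 10.68 on arrays 1 to 4, the positioning receptor GPR183 6.02, 5.56, 8.31 and 8.31, and PLAC8 7.50, 7.53, 10.03 and 9.91. S100A4, a calcium-binding protein, had 5.22, 5.31, 8.21 and 9.10, and was not called without array 3 or array 4 (limma, adjusted p = 0.109 and 0.0743). The RNA-binding protein CELF2 had 6.43, 6.61, 9.36 and 9.49, and NOTCH2NLA 6.08, 6.30, 8.90 and 8.79. Lower values on array 4 were seen for the actin-bundling protein LCP1 (10.02 on array 1 and 6.89 on array 4), the proteasome ATPase PSMC3 (8.34, 8.32, 6.55 and 5.29) and the initiation factor EIF2S3 (7.79, 7.59, 6.47 and 4.28). EIF2S3 was not called without array 1, 2 or 3 (limma, adjusted p = 0.132, 0.125 and 0.0984). EIF5A had 9.38, 9.50, 7.33 and 5.10 by 1 probe set, while another of its 3 probe sets had 7.39, 7.49, 7.18 and 7.51.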

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

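The tests of 5' loss in the mitotic genes, of naive or memory cells and of dim probe sets below were chosen after the result was seen, whereas those on S phase probe sets and on further T cell genes were set before their results were seen. Of 239 values or medians compared over the 4 arrays, 11 had an array far from the other 3 by Dixon's criterion, 6 of them array 3 and 5 array 4. Chance would give about 1 in 20 for independent values of like spread. That rate may not hold here, since arrays 1 and 2 lay closest together (r of 0.9955) and all flags fell on arrays 3 and 4. The number thus shows neither an excess nor the lack of one.

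On array 3 the ubiquitin gene UBB was low at 12.79 against 13.01 to 13.05 on the others. The T cell receptor subunit CD247 was high there at 5.73 (others 5.02 to 5.12), as were LUM at 3.16 (2.89 to 2.91) and TET1 at 3.08 (2.89 to 2.92), the last pair at background. Array 3 also had the highest means of the polyadenylated spike-in controls lys, at 6.81 (others 4.37 to 4.66), and phe, at 7.68 (others 5.05 to 5.31). The hybridisation control bioB, which was not flagged, had means of 6.34, 6.29, 8.03 and 6.98 on arrays 1 to 4. The rise on array 3 was thus not limited to the polyadenylated controls, and its cause was not tested. On array 4 the MHC class II transactivator CIITA was high at 6.39 (others 5.39 to 5.54), RFXAP at 3.89 (3.66 to 3.69) and SFTPC at 5.85 (at most 5.13). NFKB2 was low there at 4.49 (others 5.03 to 5.13). The median deviation of red cell and platelet genes on array 4 was 0.26, against -0.09 to -0.05 on the others.

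Proliferation genes were lower on arrays 3 and 4, with 26 of 26 S phase genes and 29 of 30 genes of G2 and mitosis lower on both than on arrays 1 and 2, against 43.4% of all genes above background. Loss of 5' RNA, as the signals of ACTB and GAPDH would show, is a candidate cause, and since it was larger on array 4 it should lower a list further there. For S phase genes with several probe sets above background, the least lowered probe set still deviated by -0.59 on array 4. This lay below the range of matched random lists (-0.41 to 0.38, 8 genes), the outcome set beforehand as going against 5' loss as the whole cause. It cannot decide, because probe positions along the transcripts were not used and the whole S phase list also had a median of -0.59 on array 4. S phase genes fell further from array 3 to array 4 (-0.22, 95% bootstrap interval over the 26 genes -0.40 to -0.09), the direction that 5' loss would give. For G2 and mitosis the median of array 4 minus array 3 was 0.10 (95% bootstrap interval over the 30 genes -0.08 to 0.28). Both intervals hold the spread between genes that move together. They hold no spread between arrays, since each compares 1 array with 1 other, and so cannot decide on a cause. The least lowered probe sets of G2 and mitosis gave -0.34 within a random range of -0.41 to 0.34. For these genes 5' loss and other causes thus cannot be told apart. Differences between individuals or samplings remain open, and no such biological explanation was tested because the design has a single group.

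The same arrays had higher naive and memory B cell genes, so a larger share of such cells after sorting is another candidate explanation of the lower proliferation genes. Of 18 members 15 were higher on both arrays 3 and 4 than on both others, where matched random lists gave a median of 6 and an upper bound of the central 99% of 11; the rise of this list had already been seen, so the count adds its extent and not a new observation. Of its abundant genes TXNIP had 9.45, 9.38, 11.89 and 11.24 on arrays 1 to 4 and FCMR 7.93, 7.91, 10.34 and 10.68, but TCL1A went the other way (12.04, 12.16, 10.61 and 11.35), as did IL4R. Over all arrays 13 of the 18 members lay above background, and 1 stands in another list. That call is made on the mean over the arrays, arrays 3 and 4 included, and does not show which cells held the transcripts. Whether GC B cells change these genes themselves was not tested. The sort would remove naive or memory cells only if its gate did, and the gate is not given in the sources used here.

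T cell genes were higher on array 3, where CD3D reached 7.72 against 5.26 to 6.21 on the others, while LCK, also known in B cells, was lowest there at 8.65. The list's median deviation of 0.22 lay above random lists of like mean (-0.12 to 0.13), which had already been seen and is no new observation. Its 11 members at background, part of the same list, also lay above random genes at background (0.19, against -0.11 to 0.16). The rise was thus larger than that of random genes of like signal. The list was taken up because of this rise, so the comparison is no independent test of a general rise of dim probe sets and cannot decide on it. With T cells among the sorted cells other T cell genes should also peak on array 3, but 2 of 13 such genes outside the list did, where random lists gave a median of 3 and an upper bound of the central 99% of 7. This gives no support to T cells, and by the bound set beforehand (at or below the random median) would exclude them, but 2 lies within the random spread and 9 of the 13 genes lay at background, where a small share of cells would not show. T cells thus remain a candidate source that cannot be told apart from other causes.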

How the results depend on the processing

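Leaving out arrays 3 and 4 was chosen after the data were seen; the other settings were planned. No paired analysis was possible because all 4 arrays form a single group. The count of genes above background was 4848 to 5118 on leaving out 1 array and 4895 to 5162 on averaging a pair of arrays. It was 5429 without arrays 3 and 4, 4354 with the median probe set, and 4336 to 5608 over the background levels tried. Without probe sets of suffix x or s it was 2863, of 8371 genes left, since fewer genes were tested and others lost their brightest probe set. The lists with fewer members at background then numbered 11 in place of 17. By construction a top 10% class held 945 genes and a top 2% class 179, with 14 and 3 lists enriched. The top 2% class lost the results of GC, B cell, S phase, antigen receptor signalling, immediate early, proteasome and ZNF genes, and the top 10% class gained those of naive and memory, dark zone, G2 and mitosis, repair, anti-apoptotic and, at background, Toll-like receptor genes. The median r between arrays was 0.943 over genes above background, and 0.957 to 0.973 on leaving out 1 array. It was lowest without array 3, as the pairs left then had r of 0.9955 (arrays 1 and 2), 0.9573 (arrays 1 and 4) and 0.9565 (arrays 2 and 4). Why array 4 had the lower r was not tested. The other totals stayed within a factor of 1.5, but 73 values of single lists moved further, mostly counts above background. Of the list results, 14 lost and 2 gained their call without suffixes x and s, 5 and 2 with the median probe set, and 6 and 2 with the 90th percentile as background. Those lost without suffixes x and s were the top class results of S phase, antigen receptor signalling, immediate early and ZNF genes, and the background results of GC, naive and memory, dark zone, NK, endothelial, repair, MHC class II, Polycomb, type I interferon and ZNF genes. Subtracting array medians is void, since it moves a gene and its background level alike.

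Of 1038 list genes 944 were called, and 882 (93.4%) kept the call whichever array was left out and 893 (94.6%) whichever pair was averaged. Of 194 genes named in the text 181 were called and 166 kept the call whichever array was left out. With the median probe set the mean turned below the background level for IGFBP7 (-1.87), CYP3A4 (-1.26), COL1A1 (-0.84), TAL1 (-0.83), MBP (-0.78), GATA2 (-0.66), GRIN1 (-0.64), CIITA (-0.54), PAX8 (-0.51), MCL1 (-0.44), CELF2 (-0.42), BCL2 (-0.16), PCDH9 (-0.15), SFN (-0.086), SFTPC (-0.0048) and HOXD9 (-0.0015), because their dimmer probe sets then count. It also turned, to a call below the level, for VAV2 (-0.55), NFKB2 (-0.43) and IRF4 (-0.28), and without a call for CCND2 (-0.080), all 4 not called before. Without arrays 3 and 4 CCR7 (-0.77) and CCND2 (-0.32) turned to a call below the level and CCNE2 (0.45) to one above it. Without suffixes x and s it turned for CYP3A4 (-1.08), HUWE1 (-1.01), TAL1 (-0.76), NACA (-0.60), GATA2 (-0.59) and MCL1 (-0.37), whose brightest probe sets are of that type. With the 99th percentile as background it turned for HOXD9 (-0.14), TAL1 (-0.089) and PRDM1 (-0.065), and with unrelated tissues for HOXD9 (-0.13), TAL1 (-0.087) and PRDM1 (-0.063), as both raise the level. Among other named genes a call was lost for 3 with the median probe set, 10 with the 99th percentile and 8 with unrelated tissues.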

Other observations

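Leaving out arrays 3 and 4 and naming single genes outside the highest and lowest of a list were chosen after the data were seen, while the other tests were fixed before. Genes that interferons induce gave a mixed picture, with 6 of 16 members above background by limma and 8 at background. The antiviral GTPase MX1 had 9.14 ± 0.38 (SD, n = 4), the ubiquitin-like modifier ISG15 7.89 ± 0.14 and IRF7 6.92 ± 0.33, whereas IFIT1 (3.47 ± 0.13) and IFI44L (3.18 ± 0.12) lay at background, and neither class was enriched. Chromatin enzymes of the Polycomb and DNA methylation list lay above background for 10 of 15 members and at background for 1 (Fisher's exact test, adjusted p = 0.00774), a depletion lost with arrays 3 and 4 averaged (adjusted p = 0.0753) or left out (0.0627) and with the 99th percentile as background (0.123). The histone chaperone RBBP7 had 9.45 ± 0.36, the Polycomb subunit SUZ12 9.11 ± 0.21 and the maintenance methyltransferase DNMT1 8.27 ± 0.61. DNMT3A had 4.36 ± 0.39 and was called below the level (limma, adjusted p = 0.0333), except without array 1, 2 or 4 (0.107, 0.118 and 0.0866), and the demethylase TET1 lay at background (2.95 ± 0.09).

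Toll-like receptors had 0 of 8 members above background by limma, also at an unadjusted p under 0.05, and 7 at background (Fisher's exact test, adjusted p = 0.0505), which passed with the 90th percentile as background (adjusted p = 0.0184) and among the tests with a top 10% class (0.045). TLR7 had 3.29 ± 0.26 and TLR4 3.03 ± 0.22, whereas TLR1 had 5.37 ± 0.55 and was called above background without array 4 (limma, adjusted p = 0.0255). Protocadherins, adhesion proteins of neurons, had 23 of 27 at background (Fisher's exact test, adjusted p = 0.000121), with PCDH9 above it at 5.87 ± 0.21 by 1 of its probe sets and PCDHB8 lowest at 2.98 ± 0.07. Zinc finger genes of the ZNF series had 114 of 212 at background (Fisher's exact test, adjusted p = 0.0268) and 1 in the top class, ZNF706 at 9.47 ± 0.22 (adjusted p = 0.00967 for depletion), down to ZNF675 at 2.85 ± 0.22. Both ZNF results were lost without probe sets of suffix x or s (Fisher's exact test, adjusted p = 0.189 and 0.13). Of 49 receptor genes that set the background level, OR3A3 was the highest at 5.21 ± 0.39 and was not called without array 3 or array 4 (limma, adjusted p = 0.098 and 0.0687), and TAS2R10 was lowest at 2.97 ± 0.16.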
